A study of Mus musculus with 4 samples.

How the data were processed

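Each of the 4 libraries came from RNA of alveolar macrophages of BALB/c mice, 2 from untreated mice and 2 from mice injected with BNL hepatocellular carcinoma cells 21 days earlier. Per the labels' protocols, cDNA bound to beads was cut with NlaIII, which cuts at CATG, an adapter was ligated, and EcoP15I released a short tag next to the cut site, which was amplified by PCR and sequenced. A tag thus counts a transcript at an NlaIII site, by design the one nearest its 3' end, and carries the strand of the transcript. The labels do not say whether the 2 libraries of a group came from separate mice or from separate pools, so p-values measure only the spread between these samples, which may be technical. The untreated mice are not described as sham-injected, so injection and metastasis are not separated by this design.

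The deposited values are raw tag counts, per the file headers and the values, one count per tag of 21 bases with a gene symbol and a RefSeq accession. The genome build is mm9 per the submitters' processing notes, and the matching tool and count filter are not given in the sources used here. The 4 tables list the same 30627 tags, of which 15785 have a count in at least 1 library. No library holds a count of 1, while 2045 to 2766 tags per library have a count of 2, so tags read once are absent from the deposited counts. Tags that the deposited tables do not list were not analysed here. PCR copies were not told apart by molecular identifiers, so intervals and floors cover counting error only.

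Gene names were taken from the RefSeq accession of each tag through a table of NCBI RefSeq genes (29346 tags), from the symbol (429 tags) or an older symbol (115 tags), and 737 tags kept the deposited symbol. Counts of all tags of a gene were summed, which gave 7280 genes with counts. Each tag was also searched, after CATG, in GENCODE M21 transcripts (GRCm38), and coordinates given in the text come from that match. Tags at the last NlaIII site of a transcript of their own gene held 84.6% and 77.9% of the counts in the day 21 metastasis libraries of replicates 1 and 2 and 78.5% and 72.7% in the untreated ones. Tags that matched their gene alone held 69.3% to 81.4%. The 622 tags that matched no transcript on the sense strand were kept in the counts. They held 3.92% and 8.76% of the counts in the day 21 metastasis libraries and 11.6% and 12.5% in the untreated ones, mostly in the tag deposited as Gm3903. BALB/c sequence that differs from the reference can remove a tag, in the same way in every library.

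Differences were tested with edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, TMM normalisation, the filter filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over the 2993 genes left, with a threshold of 0.05 and group as the only term. TMM factors were 0.988 and 0.864 for day 21 metastasis and 1.05 and 1.12 for untreated libraries. The biological coefficient of variation was 0.482, with 2 residual degrees of freedom per gene before sharing across genes. Log2 changes are day 21 metastasis minus untreated, with the standard error taken as the change divided by the square root of F. For a gene listed at 0 in both untreated libraries the fold is a bound on the untreated side only, with the day 21 mean taken without its own error. Its floor per library is the largest count that would leave each of its listed tags at 0 or 1 reads with a probability of 5%, with equal shares per tag, which is 4.74 counts for 1 listed tag, 6.43 for 3 and 9.05 for 8. Each library counted as 1 replicate. The 2 libraries of a group differed by more than counting noise (chi-square per degree of freedom 59.4 for untreated and 44.1 for day 21 metastasis). Amplified tags would exceed that noise in technical repeats too, so this does not show that the libraries are biological replicates.

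Before the data were examined, 37 gene lists were fixed, 24 of pathways or cell states and 13 of cell types including other macrophages, and 24 had at least 3 tested members. These were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. The rule for named genes was also fixed then. It takes the 10 higher and 10 lower genes of smallest p with an adjusted p under 0.05, non-overlapping groups and a mean of at least 10 CPM, without predicted genes. It adds every measured leukotriene gene, up to 4 members of smallest p of each list that passed camera or is described, the 2 most abundant members of each cell-type list, and Nos2, Arg1, Il1b, Tnf, Retnla, Spp1, Siglecf, Marco and Pparg.

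The test was tried on simulated counts for the 2993 genes of this comparison, with 50 genes changed at each of 4 fold sizes. It recovered 2% of 50 genes changed 2-fold, 8% of 50 changed 4-fold, 72% of 50 changed 8-fold and 84% of 50 changed 16-fold, with 0 calls among 2793 unchanged genes and 0 calls when nothing was changed. The simulated libraries were independent and each gene varied as the fitted trend over abundance. Spread of single genes about that trend and shared deviations of same-numbered libraries were not simulated, so false calls in the real data are not measured. Alternatives were another scaling, filter, test or threshold, the replicate number as a block, 1 test per tag, and each library left out in turn. Counting by last-site tags or by tags of 1 gene and a correction for tag GC content were added after the data were seen. DESeq2 1.42.0 and limma-voom served as other tests. Figures were drawn with matplotlib 3.10.9.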

Results

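Gene expression was measured by serial analysis of gene expression (SAGE) in mouse alveolar macrophages, the resident phagocytes of the air spaces of the lung. The cells came from BALB/c mice that were untreated or that had received BNL cells, a mouse hepatocellular carcinoma line, into a vein 21 days earlier and carried lung metastases. Each group had 2 libraries. The total count was 1783814 and 1630776 tags in the day 21 metastasis libraries of replicates 1 and 2, and 1962569 and 2198563 tags in the untreated ones. Between 4779 and 5894 genes had counts in a library. No tag has a count of 1 in any library, so a count of 0 can stand for tags read once, and each tag of a gene listed at 0 has 0 or 1 reads. One lysosomal protease, cathepsin D (Ctsd, named because of its abundance after the values were seen), took 36.4% and 35.5% of the counts in the day 21 metastasis libraries and 24.9% and 22.4% in the untreated ones. The exact Clopper-Pearson 95% intervals of these 4 shares, which cover counting error only, were 36.35% to 36.49%, 35.46% to 35.61%, 24.87% to 24.99% and 22.37% to 22.48%. Ctsd itself did not pass the gene test (log2 change 0.83 ± 0.37 SE, adjusted p = 0.763). Libraries of 1 group were no more alike than libraries of different groups. Pearson's r was taken of log2 CPM (counts scaled to a TMM-normalised library of 1000000) over 2993 genes, which are not independent replicates. It was 0.896 between the day 21 metastasis libraries, 0.885 between the untreated libraries and 0.788 to 0.917 across groups.

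The first comparison asked which genes differ between alveolar macrophages of metastasis-bearing and untreated lungs. In the day 21 metastasis libraries Apoe, the lipid-transport apolipoprotein E, reached 2224 ± 695 CPM against 53.5 ± 35.4 CPM in untreated mice (mean ± SD, n = 2 per group). CPM are relative to the TMM-scaled size of a whole library, so a change per cell and a change in the mix of cells look alike. Cd63, a tetraspanin of late endosomes and lysosomes, was at 508 ± 141 CPM against 9.94 ± 1.56 CPM. Mmp14, a membrane-bound matrix metalloproteinase, was at 130 ± 40.2 CPM, while its untreated libraries held only 3 and 2 counts. The B and C chains of complement C1q, the starter of the classical complement pathway, had 75 and 96 counts (C1qb) and 125 and 71 counts (C1qc) on day 21 and are listed at 0 in both untreated libraries, where tags read once may be missing. Only 2 genes were lower on day 21. They were Afdn, which encodes the junction protein afadin, and Tppp3, a tubulin-binding protein, at 9.49 ± 8.38 and 18.7 ± 4.72 CPM against 93.6 ± 43.3 and 139.8 ± 77.0 CPM.

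In all, 20 genes were higher and 2 lower among the 2993 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 106 were higher and 64 lower at an unadjusted p under 0.05. The log2 change was 5.66 ± 0.73 (SE) for Cd63, 6.77 ± 0.88 for Mmp14 and 5.37 ± 0.70 for Apoe, each with an adjusted p of 3.95e-05. With Mmp14, 419 counts on day 21 stood against 5 in untreated mice, a ratio of 119.1 with a counting interval of 50.6 to 368.6 that leaves out tags read once. For genes listed at 0 in both untreated libraries, folds are bounds against the most counts per library that 0 or 1 reads of each listed tag allow. They bound the untreated side only, since the day 21 side is the mean of its libraries without its own error. With 3 listed tags each (6.43 counts), C1qc was at least 21.1-fold higher and C1qb at least 19.2-fold higher (adjusted p = 4.79e-05 and 5.72e-05). Fcgr2b, the inhibitory Fc receptor for IgG, also with 3 listed tags, was at least 8.67-fold higher, with 38 and 40 counts against 0 and 0. With 1 library left out, the lowest bounds were 17.5-fold for C1qc, 14.8-fold for C1qb and 7.50-fold for Fcgr2b. Cxcl16, a transmembrane chemokine, was 27.7-fold higher at 373.4 ± 0.99 CPM, and Ms4a7, a macrophage membrane protein, 22.4-fold higher at 243 ± 1.20 CPM. Ecm1, extracellular matrix protein 1, was 18.2-fold higher, and Lat2, an adaptor of immune receptor signalling, was 38.2-fold higher with 95 and 132 counts against 8 and 0. The log2 change was -3.27 ± 0.78 for Afdn and -2.90 ± 0.70 for Tppp3 (adjusted p = 0.0432 and 0.0460). Single libraries moved some of these values by over 1.5 times. Without untreated replicate 2 the log2 change was 6.31 for Apoe, 4.24 for Lat2 (5.26 with all libraries) and -2.16 for Tppp3. Without untreated replicate 1 it was 5.12 for Ms4a7 (4.49 with all libraries), and Lat2 was left with 0 untreated counts. Without day 21 metastasis replicate 2 it was 3.48 for Ecm1 (4.18 with all libraries) and -2.56 for Afdn, and without day 21 metastasis replicate 1 it was -4.63 for Afdn. All 22 genes had non-overlapping groups, which 31.2% of the tested genes had, against 33.3% by chance.

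The other 10 genes past the threshold were all higher. H2-Eb1, a beta chain of MHC class II, was 6.69-fold higher (6556 ± 4041 against 981 ± 441 CPM), Pla2g7, the platelet-activating factor acetylhydrolase, 14.3-fold higher, and Trem2, a lipid-sensing receptor of macrophages, 10.8-fold higher. Pf4, the platelet chemokine CXCL4, had 35 and 37 counts against 0 and 4. Igf1, insulin-like growth factor 1, was at least 3.42-fold higher and C3ar1, the receptor of complement C3a, at least 2.14-fold higher, against 6.43 and 9.05 counts per untreated library for their 3 and 8 listed tags. The bound of Igf1 was 2.17-fold without day 21 metastasis replicate 2, where the gene has too few counts to be tested, and C3ar1 has too few without either day 21 metastasis library. The bound of C3ar1 was 1.82-fold without day 21 metastasis replicate 2. With edgeR's robust prior, Igf1, C3ar1 and Rasa4 did not pass (adjusted p = 0.0588, 0.1003 and 0.0525), and with DESeq2 C3ar1 and Rasa4 did not (adjusted p = 0.0631 and 0.122). Over all settings the adjusted p ran from 0.000224 to 0.687 for Igf1, 0.000400 to 0.720 for C3ar1 and 0.000613 to 1 for Rasa4. With total counts alone none of the 10 genes of this paragraph passed. The remaining 4 were Apobec1, at least 5.47-fold higher, Cox6a2, at least 4.82-fold higher, Rasa4, with 19 and 20 counts against 0 and 2, and Ifitm1, which was 6.75-fold higher. The bound was 4.54-fold for Apobec1 without day 21 metastasis replicate 2 and 3.62-fold for Cox6a2 without day 21 metastasis replicate 1. The main tag of Ifitm1 matches transcripts of 6 genes, so its name is uncertain. The log2 change of Trem2 was 2.13 without day 21 metastasis replicate 2, 4.19 without its replicate 1 and 4.13 without untreated replicate 2 (3.44 with all libraries). That of Pla2g7 was 2.92 without day 21 metastasis replicate 2 and 4.47 without its replicate 1 (3.84 with all libraries), and that of H2-Eb1 was 1.97 without day 21 metastasis replicate 1 (2.74 with all libraries). Without untreated replicate 1 the log2 changes of Pf4 and Rasa4 were 3.77 and 3.83 (both 4.64 with all libraries), and without untreated replicate 2 both were left with 0 untreated counts. Trem2 and the last 4 fall outside the rule for named genes and were named after their values were seen, to complete the count.

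**Figure D1:**
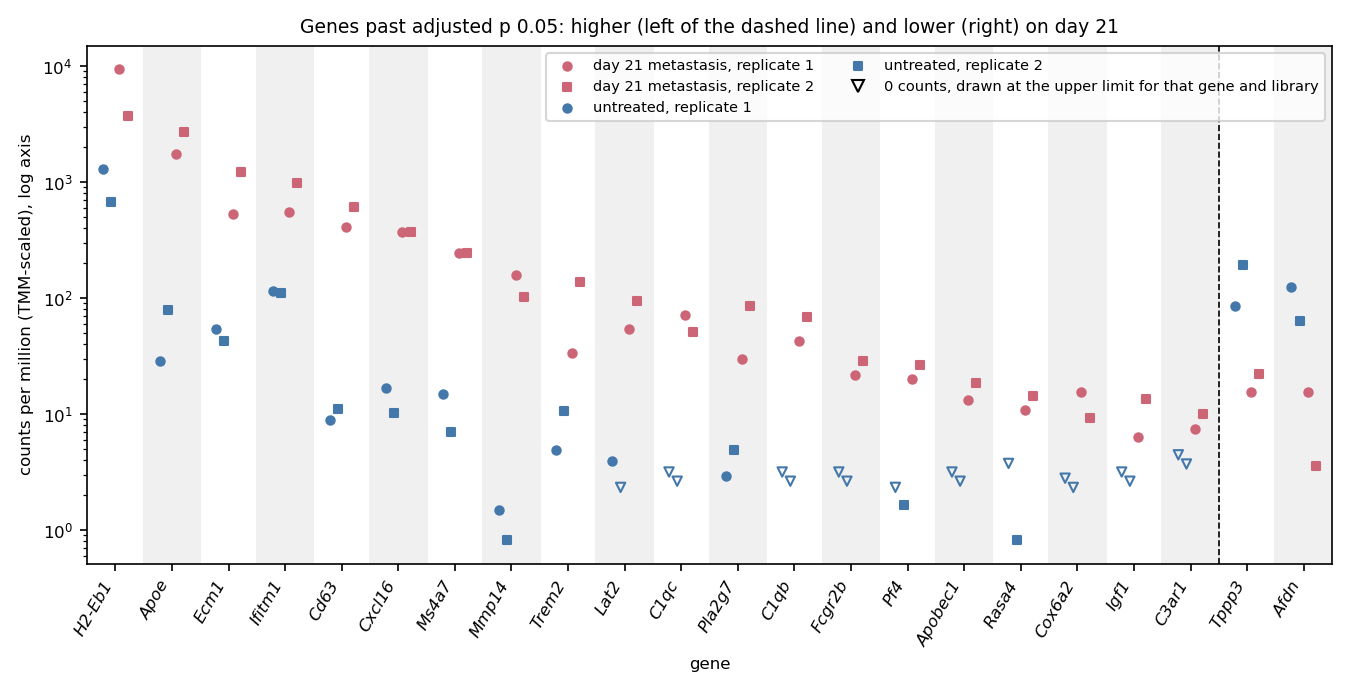
TMM-scaled CPM (log axis) of the 22 genes past the threshold in each of the 4 libraries, with colour for the group and shape for the replicate number. The 20 higher genes, left of the dashed line, have both day 21 metastasis libraries above both untreated ones, and open triangles mark 0 counts at the upper limit for that gene and library.

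These calls depended on the libraries used. Without untreated replicate 1, 0 genes passed (smallest adjusted p 0.0647, with 137 genes at an unadjusted p under 0.05), although the 22 genes kept their direction. Without untreated replicate 2, 63 genes were higher and 18 lower. Without day 21 metastasis replicate 1 the counts were 20 and 8, and without its replicate 2 they were 14 and 1. Afdn and Tppp3 were not past the threshold with upper-quartile or total-count scaling. The median tested gene had a log2 change of -0.07 with TMM scaling and -0.29 with total counts alone, and all changes given here are relative to the former.

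The tags placed the counts within the transcripts. Matched to GENCODE M21 transcripts on GRCm38, the main tag of Apoe lay on chromosome 7 at 19696449 to 19696473, in the coding sequence of the last exon (exon 3 of 3 of Apoe-205), and held 95.5% of the counts of the gene. The main tag of Mmp14 lay on chromosome 14 at 54440616 to 54440640, in the coding sequence of exon 10 of 10. For C1qc and C1qb the main tags lay on chromosome 4, at 136890079 to 136890103 and 136880277 to 136880301, each in exon 3 of 3. The main tag of Cxcl16 was on chromosome 11 at 70455270 to 70455294, in the 3' UTR, and that of Tppp3 on chromosome 8 at 105467570 to 105467594, also in the 3' UTR. The main tag of Cd63 (chromosome 10, 128912211 to 128912235) also matches its pseudogene Cd63-ps. Of the 22 genes, 20 had a main tag that matched 1 gene, and 10 had their main tag at the NlaIII site nearest the 3' end of the transcript shown.

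Gene lists fixed before the data were examined were then compared as groups. Of 24 lists, 8 passed camera with a preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.317). With an estimated correlation camera rests on the 2 residual degrees of freedom of this design, so few lists could pass. For MHC class II genes its unadjusted p was 0.145 against 0.022 with the preset, although their estimated correlation was negative (-0.13). The MHC class II list did not pass with the preset. In the 8 lists that did, the estimated correlation was above the preset, from 0.055 (matrix proteases) to 0.26 (ribosomal proteins). Correlation between genes and the few degrees of freedom thus cannot be told apart as reasons for missing the threshold. The preset of 0.01 is an assumption. Markers of monocyte-derived and interstitial macrophages formed the list with the highest median. Of its 10 tested members, 5 rose (Apoe, C1qb, C1qc, Ms4a7 and Trem2), 0 fell and 5 did not pass, while 9 were higher when adjusted over the list alone. All 10 had a positive log2 change, with a median of 3.39, which was the same with C1qb and C1qc set at their bounds. The list passed camera with a preset correlation of 0.01 (adjusted p = 4.29e-26) but not with an estimated correlation (adjusted p = 0.317). Among complement proteins and Fc receptors, 4 of 11 members rose (C1qb, C1qc, Fcgr2b and C3ar1) and 7 did not pass, with 5 higher when adjusted over the list alone. The median log2 change of that list was 0.91 (camera adjusted p = 3.74e-11 with the preset correlation, adjusted p = 0.333 with an estimated correlation). C1qa, named after its values were seen, was below the filter, with 10 and 7 counts on day 21 and 0 and 0 in untreated mice.

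The chemokine, matrix protease and lysosome lists had positive medians and passed camera with the preset correlation only (adjusted p = 0.333, 0.342 and 0.509 with an estimated correlation). Of 5 tested chemokines, Cxcl16 and Pf4 rose, 3 were higher when adjusted over the list alone, and the median log2 change was 2.95. Ccl9 had a log2 change of 2.95 ± 0.86 (SE) and did not pass over all genes (adjusted p = 0.149), although it did without untreated replicate 2 (log2 change 4.04, adjusted p = 0.00643). Its log2 change was 1.48 without day 21 metastasis replicate 2 and 3.74 without its replicate 1. The chemokine list passed camera with the preset correlation (adjusted p = 1.31e-08) and not with an estimated correlation (adjusted p = 0.333). Of 10 matrix proteases and inhibitors, 1 rose (Mmp14), and 3 were higher when adjusted over the list alone. Plau, the urokinase plasminogen activator, and Ctsb, the lysosomal protease cathepsin B, had log2 changes of 2.96 ± 0.87 and 1.55 ± 0.52 and did not pass over all genes (adjusted p = 0.159 and 0.350), although Plau did without untreated replicate 2 (log2 change 3.93, adjusted p = 0.0363). The median of this list was 0.94 (camera adjusted p = 1.12e-05 with the preset correlation, adjusted p = 0.342 with an estimated correlation). It was the 1 list past the test for change in either direction of fry (adjusted p = 0.0434), whose directional test no list passed (smallest adjusted p = 0.332). Of 35 lysosome and phagosome genes, 1 rose (Cd63) and 28 had a positive log2 change, with a median of 0.65 and 3 higher when adjusted over the list alone. Lgmn, the protease legumain, was at 226 ± 53.7 against 47.3 ± 30.8 CPM and did not pass over all genes (adjusted p = 0.163). Its log2 change of 2.25 ranged from 1.71 to 3.17 with 1 library left out. The lysosome list passed camera with the preset correlation (adjusted p = 3.78e-06) and not with an estimated correlation (adjusted p = 0.509).

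Lipid-related lists had smaller medians, with 1 called gene each, and passed camera with the preset correlation only (adjusted p = 0.509 for both with an estimated correlation). Of 16 genes of lipid handling and cholesterol efflux, 1 rose (Apoe, also the 1 member higher when adjusted over the list alone), and the median log2 change was 0.48. Pltp, the phospholipid transfer protein, was at 4494 ± 2196 CPM on day 21 and 2082 ± 871 CPM in untreated mice and did not pass (adjusted p = 0.893). This list passed camera with the preset correlation (adjusted p = 0.00429) and not with an estimated correlation (adjusted p = 0.509). Of 6 prostaglandin and other lipid-mediator genes, 1 rose (Pla2g7), which breaks down platelet-activating factor and makes no prostaglandin. Adjusted over the list alone, 2 were higher. Ptgir, the prostacyclin receptor, had a log2 change of 3.04 ± 0.83 and an adjusted p of 0.0940 over all genes, and it passed with the likelihood ratio test. That test called 2 members of the list higher, DESeq2 1 and limma-voom 0. The median was 0.29 (camera adjusted p = 0.0276 with the preset correlation, adjusted p = 0.509 with an estimated correlation). Without day 21 metastasis replicate 2 the camera adjusted p of the lipid-handling and prostaglandin lists was 0.107 and 0.0605, and without untreated replicate 1 it was 0.0665 and 0.453.

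Cytosolic ribosomal proteins formed the 1 list with a negative median that passed camera with the preset correlation, and it did not pass with an estimated correlation (adjusted p = 0.524). Of 60 tested members, 0 rose and 0 fell in edgeR's quasi-likelihood test, with 1 lower and 0 higher at an unadjusted p under 0.05, and 0 passed DESeq2, limma-voom or the likelihood ratio test. Still, 56 of the 60 had a negative log2 change, with a median of -0.66 (camera adjusted p = 9.53e-07 with the preset correlation, adjusted p = 0.524 with an estimated correlation). Adjusted over the list alone, 0 passed. Fau, whose product is cleaved to a ribosomal protein of the small subunit, was at 213 ± 111 CPM on day 21 and 515.6 ± 1.14 CPM in untreated mice. Rps20 was at 21.4 ± 2.03 against 53.9 ± 32.5 CPM. With 1 library left out, log2 changes ranged from -1.88 to -0.79 for Fau (-1.28 with all libraries). For Rps20 they ranged from -1.84 to -0.50 (-1.33 with all libraries). Ribosomal protein genes have many near-identical pseudogenes, and only 12 of the 60 had a main tag that matched 1 gene. The median of those 12 was -0.69.

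**Figure D2:**
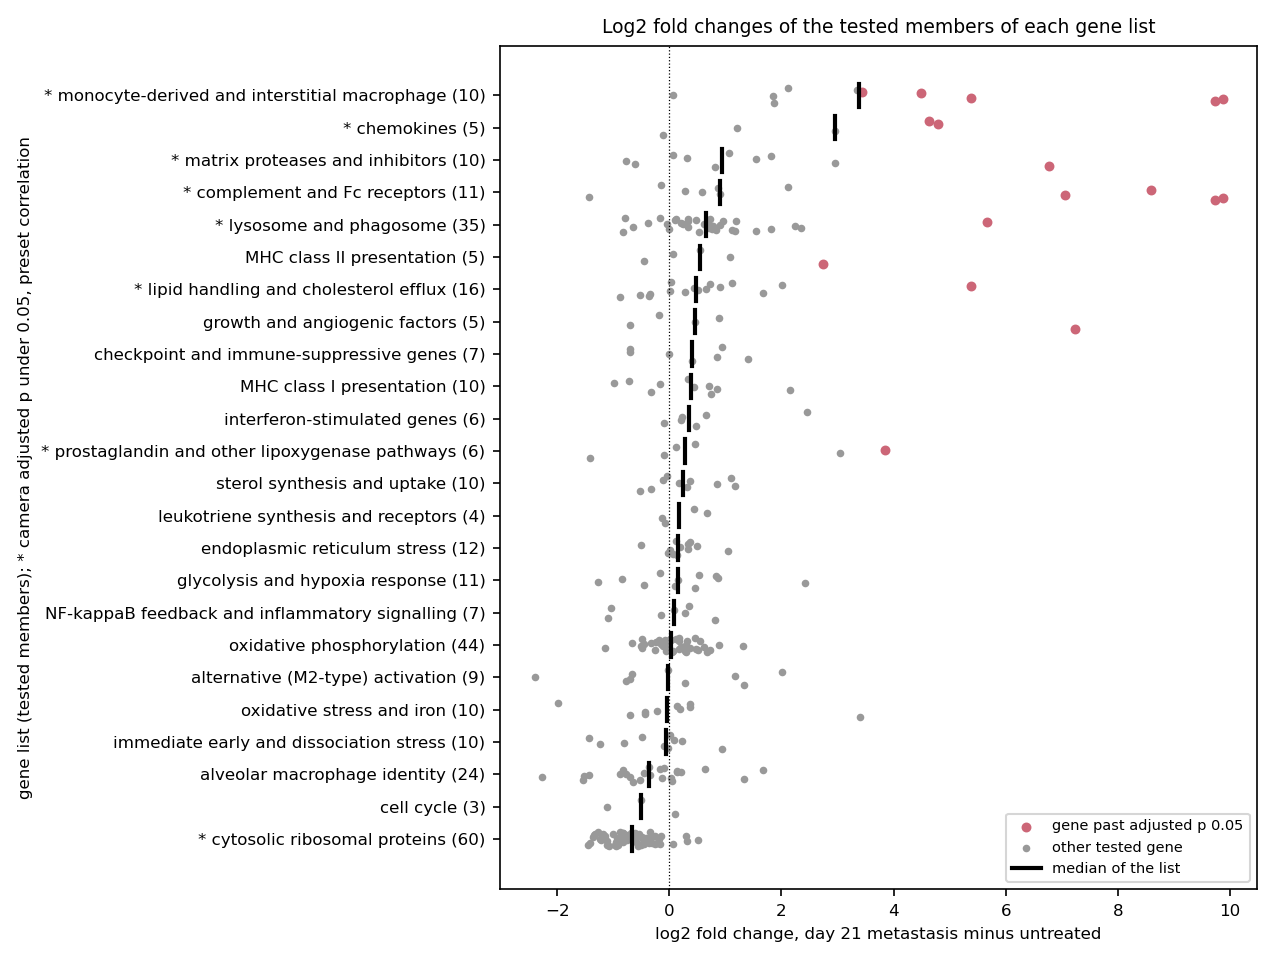
Log2 fold change, day 21 metastasis minus untreated, of each tested gene in the 24 lists with at least 3 tested members. Genes at 0 in both untreated libraries, such as C1qc and C1qb, are drawn at the fitted change and not at their bound. For C1qc these are 9.87 and 4.40, so such points are not measured folds. Points in red passed an adjusted p of 0.05, black bars are list medians, and an asterisk marks the 8 lists past camera with the preset correlation (0 pass with an estimated one), of which the macrophage list at the top has the highest median, 3.39, and the ribosomal list at the bottom the lowest, -0.66.

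Markers of alveolar macrophages themselves did not pass as a list. Of 24 tested members, 0 were called by edgeR's quasi-likelihood test, with 2 higher and 3 lower at an unadjusted p under 0.05, and 0 passed DESeq2, limma-voom or the likelihood ratio test. Adjusted over the list alone, 0 passed. The median log2 change was -0.35, with 16 negative and 8 positive values (camera adjusted p = 0.166). Krt79, a keratin of alveolar macrophages, was at 55.7 ± 49.6 CPM on day 21 and 269.5 ± 83.9 CPM in untreated mice (adjusted p = 0.204, and 0.0176 without untreated replicate 2). Its log2 change of -2.27 was -1.54 without day 21 metastasis replicate 2 and -3.64 without its replicate 1. In the same list, the transcription factor gene Bhlhe41 was at 54.1 ± 23.2 and 17.0 ± 7.23 CPM (adjusted p = 0.711). Siglecf, a surface marker of these cells, was at 20.5 ± 0.82 and 32.3 ± 6.88 CPM, and Pparg, their lineage-defining nuclear receptor, at 17.2 ± 4.93 and 24.5 ± 11.0 CPM, with a change of sign without untreated replicate 2 (log2 change 0.065). The scavenger receptor gene Marco had 2 counts in untreated replicate 1 and 0 in the other 3 libraries.

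Leukotrienes are lipid mediators made from arachidonic acid, and the list of genes for their synthesis and receptors was compared next. Of its 4 tested members, 0 changed in edgeR's quasi-likelihood test, at an unadjusted p under 0.05, or in DESeq2, limma-voom or the likelihood ratio test, and 0 passed when adjusted over the list alone. Alox5, the 5-lipoxygenase that starts leukotriene synthesis, was at 17.7 ± 7.24 CPM on day 21 and 18.6 ± 5.49 CPM in untreated mice, a log2 change of -0.08 with a 95% interval of -1.57 to 1.41. Alox5ap, which presents arachidonic acid to that enzyme, was at 83.1 ± 2.69 and 90.4 ± 81.4 CPM, a log2 change of -0.12 (-1.52 to 1.28). Ltc4s, leukotriene C4 synthase, was the most abundant member at 1719 ± 953 and 1081 ± 530 CPM, a log2 change of 0.67 (-0.52 to 1.85). Cysltr1, a receptor of cysteinyl leukotrienes, was at 12.2 ± 10.2 and 9.12 ± 6.54 CPM, a log2 change of 0.44 (-1.23 to 2.12). The adjusted p of each of the 4 was 0.998. The list had a median log2 change of 0.18 (camera adjusted p = 0.543).

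Other genes of leukotriene synthesis and response were close to or below the depth of these libraries. Lta4h, the hydrolase that makes leukotriene B4, was at 2.28 and 0 CPM on day 21 and 2.45 CPM in both untreated libraries, too low to be tested. The phospholipase gene Pla2g4a had counts only in untreated replicate 1 (0.98 CPM). The leukotriene B4 receptor gene Ltb4r1 and Ptgr1 were listed at 0 in all 4 libraries. In simulated data for the 2993 genes, 2% of genes changed 2-fold, 8% of those changed 4-fold and 72% of those changed 8-fold were recovered, so 2-fold and 4-fold differences were rarely detectable with 2 libraries per group. Leaving out 1 library turned the sign of each of the 4 tested members. The log2 change of Alox5 was 0.35 without day 21 metastasis replicate 1 and 0.28 without untreated replicate 2, and for Cysltr1 the same omissions gave -0.80 and -0.13. Alox5ap was at 1.36 without untreated replicate 2, and Ltc4s at -0.02 without day 21 metastasis replicate 2.

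**Figure D3:**
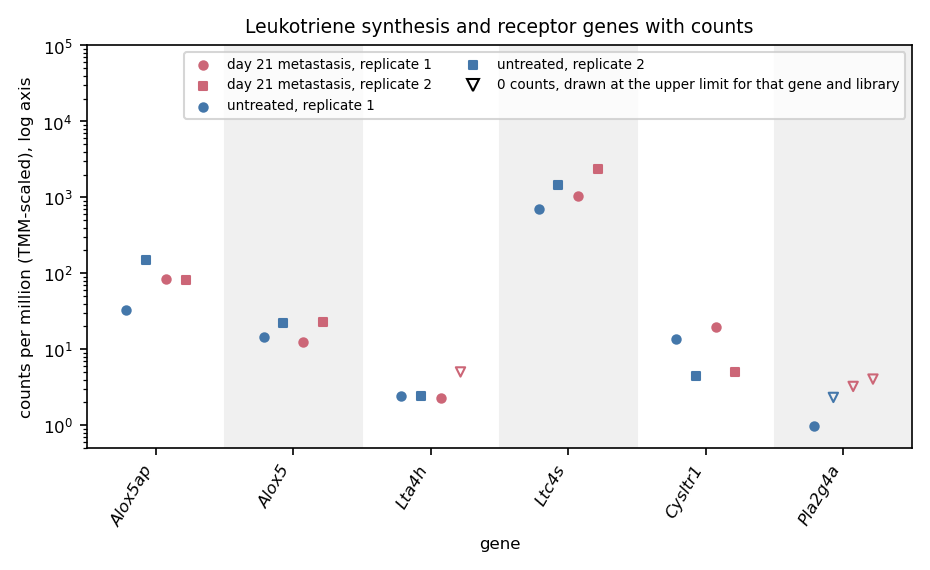
TMM-scaled CPM (log axis) of the 6 leukotriene genes with counts in each of the 4 libraries, with colour for the group and shape for the replicate number. The groups overlap for Alox5ap, Alox5, Ltc4s and Cysltr1, and open triangles mark 0 counts at the upper limit for that gene and library.

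Markers of other cells that a macrophage preparation could hold mostly had no counts or no listed tag, and those without a listed tag could not be measured. Across the 13 lists of other cell types, 6 genes were called, all higher, of which 5 belong to the macrophage list described above and Pf4 to the erythroid and platelet list. Pf4 is also counted among the chemokines. Without untreated replicate 1, 0 of these genes passed, and without untreated replicate 2, 10 did. The erythroid and platelet list (9 of 13 listed) had 4 members with counts and 2 tested, Pf4 and Hba-a1, so Pf4 alone cannot be read as platelets. The endothelial list had 0 members with counts among 7 of 11 that are listed. The B cell (6 of 12 listed), natural killer cell (5 of 11), and eosinophil, basophil or mast cell (6 of 12) lists had 1 member each with counts, and fibroblast and smooth muscle (14 of 14) had 2, all below the filter. Among T cell genes (5 of 14 listed), Cd2 was the 1 member with counts, so its values alone cannot be read as T cells. It was at 13.8 ± 1.42 CPM on day 21 and 96.5 ± 46.9 CPM in untreated mice. Cd2 did not pass (adjusted p = 0.0691), although it did with DESeq2 and with the likelihood ratio test. Epcam, an epithelial adhesion molecule, was at 12.2 ± 10.2 and 40.2 ± 18.7 CPM (adjusted p = 0.768), and Napsa, of type 2 epithelium, at 3.21 ± 4.53 and 3.19 ± 2.43 CPM. The neutrophil genes Camp and S100a9 were at 160 ± 128.5 and 12.2 ± 9.97 CPM on day 21 and at 74.8 ± 92.6 and 6.13 ± 8.67 CPM in untreated mice, and both passed without untreated replicate 2 (adjusted p = 0.00160 and 0.0165) and changed sign without day 21 metastasis replicate 2 (log2 changes -0.086 and -0.25). The alpha-globin gene Hba-a1 was at 42.7 ± 27.3 and 91.1 ± 82.3 CPM, and Irf8, of dendritic cells, at 22.0 ± 14.2 and 9.24 ± 5.43 CPM. Leaving out 1 library moved the log2 change of Cd2 from -2.80 to -2.16 (without untreated replicate 2), that of Epcam from -1.70 to -2.94 and -1.01 (without day 21 metastasis replicates 1 and 2), and that of Irf8 from 1.23 to 1.84 and 0.40 (without the same libraries) and to 2.04 (without untreated replicate 2). It changed the sign of Hba-a1 (0.40 without untreated replicate 2) and of Napsa (1.03 without day 21 metastasis replicate 1). None of these 7 genes passed the main test, and Cd2 and Epcam alone had an unadjusted p under 0.05. The hepatocyte and hepatoma list, which covers the injected tumour line, had a listed tag for only 5 of 18 members and counts for 2 of them. Trf, which encodes transferrin, was among the most abundant transcripts in both groups, at 40886 ± 117.2 and 33987 ± 10491 CPM (adjusted p = 0.998). Afp, alpha-fetoprotein, had 3 counts in untreated replicate 2 and 0 elsewhere.

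Genes that are often read as signs of macrophage activation gave few values. Nos2, Tnf, Arg1 and Retnla had no tag listed, and Il1b had 2 counts in untreated replicate 2 and 0 in the other libraries. Spp1, osteopontin, was at 1009 ± 197 CPM on day 21 and 732 ± 660 CPM in untreated mice (log2 change 0.46 ± 0.62, adjusted p = 0.998), and the log2 change was -0.24 without untreated replicate 1 and 1.95 without untreated replicate 2. Of 22 genes of classical activation, 1 was tested and did not pass. Of 9 tested genes of alternative activation, 0 were called by edgeR's quasi-likelihood test, DESeq2, limma-voom or the likelihood ratio test, with 2 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, Clec7a, the beta-glucan receptor dectin-1, was lower, at 7.20 ± 2.92 against 38.0 ± 16.2 CPM (adjusted p = 0.255 over all genes). Chil3, a chitinase-like protein, was at 1912 ± 1223 and 762 ± 612 CPM (adjusted p = 0.823, and 0.0453 without untreated replicate 2), and its log2 change ranged from 0.49 without day 21 metastasis replicate 2 to 2.57 without untreated replicate 2. Of 5 tested MHC class II genes, H2-Eb1 alone passed, also when adjusted over the list alone. Cd74, the invariant chain, and H2-DMa, a peptide-loading chain, had log2 changes of 1.08 ± 0.66 and -0.46 ± 0.52. That of Cd74 was 0.39 without untreated replicate 1 and 2.47 without untreated replicate 2. The list did not pass camera (adjusted p = 0.0599).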

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

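The tests with last-site tags, with tags of 1 gene and with a GC correction were chosen only after the data were seen; the others were planned. The 22 called genes kept their direction wherever they were tested. With all 4 libraries, 241 of their values in the alternatives stayed past the threshold and 71 missed it, and with a library left out 46 stayed and 38 missed it. Against 20 higher and 2 lower genes, the counts were 9 and 0 with total counts alone, 36 and 5 with no filter, 34 and 7 with the likelihood ratio test, 11 and 0 with tags of 1 gene, 8 and 0 with last-site tags (16 of the 22 genes tested) and 12 and 0 at a threshold of 0.01. The higher count moved to 12 with a mean count of at least 50, which tests 12 of the 22, and to 9 with limma-voom. The lower count moved to 0 with upper-quartile scaling, with a GC correction and with 1 test per tag, and to 4 with DESeq2. With 1 library left out, 0 to 63 genes were higher, 0 to 18 lower, 0 to 10 cell-type markers were called and 0 leukotriene genes passed, as in every alternative. The extremes came without untreated replicate 1 (0, 0 and 0) and without untreated replicate 2 (63, 18 and 10). A group left with 1 library is assumed to vary like the other group. Lists past the threshold fell from 8 to 0 with an estimated correlation and to 0 with fry, and were 8 to 12 with 1 library left out. The cause of these moves was not tested except where fewer genes or samples are named.

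The labels do not say that the replicate numbers pair samples. Deviations of same-numbered libraries from their group means correlated across the 2993 genes (r = 0.540). The correlation stayed at 0.535 after removal of the trend on tag GC content, which argues against GC content as the whole cause. It stayed at 0.489 with last-site tags alone. That value cannot decide on incomplete digestion, which would lower last-site tags too. Shared handling remains open and no biological explanation was tested. With the replicate number as a block, 31 genes were higher and 9 lower, with 20 of the 22 among them. The 2 others were Igf1 and C3ar1 (adjusted p = 0.0571 and 0.0682). Krt79 (adjusted p = 0.0406) was 1 of several genes called with the block and not in the main test. With the block and a GC correction together, 89 were higher and 43 lower, including the 22, and 12 cell-type markers were called.

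Among the genes named in the text that were not called, the sign changed 4 times with all libraries and 13 times with a library left out. Changes of sign of other uncalled genes were not counted. Alox5ap was at 0.22 with the block, 0.24 with limma-voom and 0.16 with the block and GC correction, and Napsa at 0.021 with DESeq2. With 1 library left out, log2 changes ranged from -0.53 to 0.35 for Alox5, -0.83 to 1.36 for Alox5ap, -0.017 to 1.31 for Ltc4s, -0.80 to 1.45 for Cysltr1, -0.24 to 1.95 for Spp1, -0.91 to 0.065 for Pparg, -0.086 to 4.12 for Camp, -1.93 to 0.40 for Hba-a1, -0.25 to 7.41 for S100a9 and -5.76 to 1.03 for Napsa. The cause was not tested. Napsa and S100a9 had few counts, while Ltc4s and Spp1 had many, so the changes of sign were not limited to genes of low depth. The alternative pseudocounts were not run because the values are counts.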

Other observations

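The tests of scaling, of upstream tags and of another kind of macrophage were chosen only after the results were seen.

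Beyond the lists described above, most of the cell's basic programmes gave no call. Oxidative phosphorylation had 44 tested genes, 0 called and a median log2 change of 0.04, and endoplasmic reticulum stress had 12, 0 called and a median of 0.16. Glycolysis and the hypoxia response (11 genes, median 0.15), sterol synthesis and uptake (10 genes, 0.24), MHC class I presentation (10 genes, 0.38), immediate early and dissociation stress genes (10 genes, -0.06), NF-kappaB feedback (7 genes, 0.08), checkpoint and immune-suppressive genes (7 genes, 0.41) and the cell cycle (3 genes, -0.50) also had 0 calls in edgeR's quasi-likelihood test, DESeq2, limma-voom and the likelihood ratio test. At an unadjusted p under 0.05 these 9 lists held 4 higher genes and 0 lower ones. Among growth and angiogenic factors, Igf1 was the 1 gene called of 5. Over the 16 lists that did not pass camera, the adjusted p ran from 0.0599 to 0.923.

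Single genes outside those calls had large changes that did not pass. Hmox1, the haem-degrading enzyme heme oxygenase 1, had a log2 change of 3.41 ± 0.92 (SE), with 15 and 55 counts on day 21 against 2 and 8 (adjusted p = 0.0879). The log2 change was 1.98 without day 21 metastasis replicate 2, and Hmox1 passed without day 21 metastasis replicate 1 (4.19, adjusted p = 0.0194) and without untreated replicate 2 (4.53, adjusted p = 0.00643). None of the 10 tested genes of oxidative stress and iron, Hmox1 included, was called, and the list median was -0.03. Ifi27l2a, an interferon-inducible gene, was at 168 ± 32.0 CPM on day 21 and 30.7 ± 1.74 CPM in untreated mice (adjusted p = 0.0852), while the 6 tested interferon-stimulated genes had a median of 0.36. Both passed when adjusted over their list alone, and both passed with the likelihood ratio test. Ifi27l2a also passed with DESeq2, and Hmox1 did not.

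A candidate explanation for the rise of Apoe, C1qb, C1qc, Ms4a7, Trem2 and the other higher genes is a change of state of the alveolar macrophages in the metastatic lung, and another is a larger share of monocyte-derived or interstitial macrophages among the cells, whose collection and sorting the labels do not describe. The tables argue against less complete NlaIII digestion on day 21 only where a last-site tag is also last in the transcript the cells expressed. A tag that is last only in a shorter transcript cannot decide. Of the 22 called genes, 10 had their main tag last in the transcript chosen to place it. The recount covered the 14 higher genes with enough tags at the last site of at least 1 transcript. From those tags alone they kept a median log2 change of 4.66 (interquartile range 0.85), with genes at 0 in untreated mice at their bounds. Less complete digestion in untreated mice is not addressed, because it would itself lower their last-site tags. For Cxcl16, Ms4a7 and Pf4, with 1 listed tag each, and for Igf1, with counts in 1 tag, the recount uses the same counts. The remaining 448 genes counted from upstream tags alone had a median of -0.028 (interquartile range 0.96). Upstream tags thus did not rise as a whole. The smallest change or bound of the other 6 higher genes, 1.10, lay above that median by more than that range. Those 6 were selected for a rise, so this comparison alone does not decide on digestion for them. Scaling pulled by Ctsd and a few abundant genes is also argued against as the source of rises this large. For the 13 genes with counts in an untreated library, the smallest log2 change over 4 scalings was 2.50. The largest shift of the median gene was 0.27. These genes were called for large changes, so the comparison bears on size and not on which genes pass. With total counts alone, 9 of the 22 calls were kept. Of the 7 genes at 0 in both untreated libraries, C1qc, C1qb, Fcgr2b, Apobec1, Cox6a2 and Igf1 had log2 bounds of at least 1.52 under each of the 4 scalings, more than 1 above that shift, which argues against scaling for them too. C3ar1, with the smallest bound (1.10), came to 0.86, so scaling is left open for this gene alone. State and cell mixture cannot be told apart here, because the alveolar macrophage list had a median of -0.35 with an interquartile range of 0.85 and 8 of the 10 tested markers of other macrophages also had counts in untreated libraries.

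The second most abundant tag, GATACTTGGAATGACTATTAA, deposited as Gm3903 and singled out after its values were seen, matched no transcript on the sense strand. It matched the opposite strand of Actb, the beta-actin gene, on chromosome 5 at 142903462 to 142903486 of GRCm38, in exon 6 of 6, and held 3.45% and 8.07% of the counts in the day 21 metastasis libraries and 11.2% and 11.6% in the untreated ones. The counts under Gm3903 gave a log2 change of -0.72 ± 0.45 (SE) and did not pass (adjusted p = 0.998), although they did without day 21 metastasis replicate 2 (-1.56, adjusted p = 0.0188), while the log2 change was -0.12 without day 21 metastasis replicate 1.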
